A study of Mus musculus with 24 samples.

How the data were processed

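RNA of 24 samples was hybridised to Illumina Mouse-Ref-6 v1.1 bead arrays. Per the labels' protocols, fluorescent heart tissue was pooled and dissociated, 5000 cells per sample were sorted, and their RNA was amplified in 2 linear rounds and labelled with biotin. Groups and replicate numbers come from the labels. The deposited unprocessed table holds an intensity per probe and sample on a linear scale with no background correction or normalization, as its values show: 46667 rows, of which 35 repeat a probe and were averaged, for 46632 probes. The deposited series matrix holds log2 values made by the authors. Each of its columns followed the ranks of the same array's intensities (lowest Spearman correlation 0.99999), with column medians of 3.91 to 4.11. Scale (log2) and direction are thereby known, and the method of background correction and normalization is not given in the sources used here. The submitters' processing notes name limma, without a version. The files hold no detection p-values or control probes, so no probe can be called absent, and the number of arrays limits the precision. 0 columns of per-sample values were left unused.

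Intensities were corrected with limma's normexp method with an offset of 50, set to the log2 scale and quantile normalized over the 24 arrays. A probe was kept if it exceeded its array's median on at least 6 of 24 arrays (26693 probes). The offset and the floor compress differences of dim probes. The probe table gives 1 gene symbol for 29976 probes, several for 10 and none for 16646. Of the probes with a gene, 29921 matched the reference gene table by Entrez number and took its current symbol and 65 kept the table's own. Probes with several symbols or none were not named. The brightest probe by its mean over all arrays stood for its gene, which left 12982 genes. The probes of Dcx, Hk1, Ncam1 and Pdgfra at E10.5 and of Hspb1 and Syt1 at E17.5 disagreed in sign. Probes of other named genes agreed in sign but disagreed in size. At E10.5 a further probe gave 0.042 for Serpinf1, 0.028 for Matn4, 0.055 for Tbx2 and -0.037 for Jph2. At E17.5 a further probe gave -0.1 for Vsnl1, -0.276 for Upk3b, 0.729 for Car3 and 0.938 for Btn1a1. The probes of Nppa gave like sizes at each stage. Signals up to the top of the scanner's range were kept, so differences of the brightest genes can be understated. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.

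A linear model with 4 group means was fitted with limma's lmFit and eBayes (20 residual degrees of freedom, a prior of 2.87). 5 contrasts were taken: AVC minus WM at E10.5, AVN minus WM at E17.5, the difference between these, and the stage difference within the Tbx3-sorted and within the WM groups. Benjamini-Hochberg adjustment was made per contrast, with an adjusted p under 0.05 as the threshold. 24 gene lists, fixed before the data were examined along with the design, the alternatives and the rule for named genes, were tested with limma's camera at a preset inter-gene correlation of 0.01, and adjusted over all 120 tests. 60 tests passed, 15 of them at E10.5, 14 at E17.5, 15 in the difference between stages, 10 in the Tbx3-sorted stage contrast and 6 in that of WM. With a correlation estimated per list 2 passed, the chamber list at E10.5 and the atrial list at E17.5. Counts "over the list alone" repeat the adjustment within a list. The lists cover conduction and node, chamber, atrial and ventricular myocardium, sarcomere, calcium handling, 3 lists of energy metabolism, cell cycle, BMP and TGF-beta, Notch and Wnt signalling, axon guidance, immediate early genes, and markers of neurons, Schwann cells, endothelium, mesenchyme, epicardium, smooth muscle, erythroid cells, leukocytes and epithelium. Tbx3 and Nppa drove the sorts, so they are in no list and their differences check the labels only. They stay in the counts of genes and in the closing section's values.

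The named genes are Tbx3 and Nppa, the 8 largest differences in each direction per tissue contrast among called genes without overlap of the groups, up to 4 called members per list, the 5 largest in each direction of the difference between stages and the 6 largest of each stage contrast, leaving out clone and accession names, with conduction and chamber genes nameable whatever their test. Not every such gene is named: of the genes that this rule gives, those named were picked for length after their values and the samples far from their group had been seen. Values of a gene named in a further contrast, Tnnt2, the probes that disagreed and the neighbours of Nppa and Tbx3 fall outside this rule and were chosen after values were seen. Gene order comes from the reference table of assembly GRCm38.p6 (12961 of the tested genes had a position), and no coordinates are given, since the array's build is not given in the sources used here.

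The fit was tested on simulated data with 12982 genes of which 200 were changed, 50 per size. For AVC minus WM at E10.5 it recovered 54% of log2 changes of 0.5, 96% of those of 1 and 100% of those of 2 and 3. For AVN minus WM at E17.5 it recovered 66% at 0.5, 98% at 1 and at 2, and 100% at 3. Of the genes called, 5.91% and 3.21% were not among those changed. The simulated noise was normal, independent between genes and equally wide in all groups, and far fewer genes were changed than were called in the data. These rates therefore need not hold for the data. Alternatives covered the background correction, the normalization, the deposited values, the filter, the probe rule, the samples in the fit, the variance model, array weights, blocks, thresholds and leaving out each sample.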

Results

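Gene expression was measured on 24 single-colour mouse bead arrays, each loaded with amplified RNA from 5000 sorted fluorescent heart cells. 6 samples each came from working myocardium (WM) and atrioventricular canal myocardium (AVC) of embryos at E10.5, and from WM and atrioventricular node myocardium (AVN) of fetuses at E17.5. WM is the contracting muscle of the heart chambers, and cells were sorted for a green fluorescent reporter driven by a bacterial artificial chromosome (BAC) that carries the gene of atrial natriuretic peptide, Nppa. AVC is the slowly conducting muscle between atria and ventricles, and AVN the node that delays the impulse there later; these cells were sorted for a reporter on a BAC with the transcription factor gene Tbx3. Tissue and reporter line were therefore the same split at each stage. Median unprocessed intensity was 110.3 to 132.8 units at E10.5 and 54.7 to 61.3 at E17.5, so stage and scan brightness went together as well. Correlations between replicates, across genes, were 0.960 to 0.996 for WM at E17.5 and 0.970 to 0.994 for AVC at E10.5, with 0.983 to 0.996 for WM at E10.5 and 0.980 to 0.991 for AVN. The labels do not say that the 6 samples of a group came from separate litters, so p-values measure the spread between these samples only. Differences are given as log2 differences of normalized intensity ± standard error (SE) with 6 arrays per group, and a log2 difference of 1 is a 2-fold difference.

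The reporter genes differed in the direction of the sorts. Tbx3 read 11.53 ± 0.62 (SD, n = 6) on the log2 scale in AVC and 9.57 ± 0.30 in WM at E10.5, a log2 difference of 1.95 ± 0.27. At E17.5 it read 11.35 ± 0.35 in AVN and 7.19 ± 0.59 in WM, a difference of 4.16 ± 0.27. Nppa was lower than in WM by a log2 difference of -3.37 ± 0.66 in AVC and -6.59 ± 0.66 in AVN. Since both genes drove the reporters by which the cells were sorted, their differences check the labels and are no finding. Nppa varied widely in the Tbx3-sorted groups. AVC replicate 6 read 8.54 where the other 5 AVC samples lay between 11.72 and 12.52, and AVN replicates 1 to 3 had a mean of 6.90 against 10.15 for replicates 4 to 6.

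**Figure D1:**
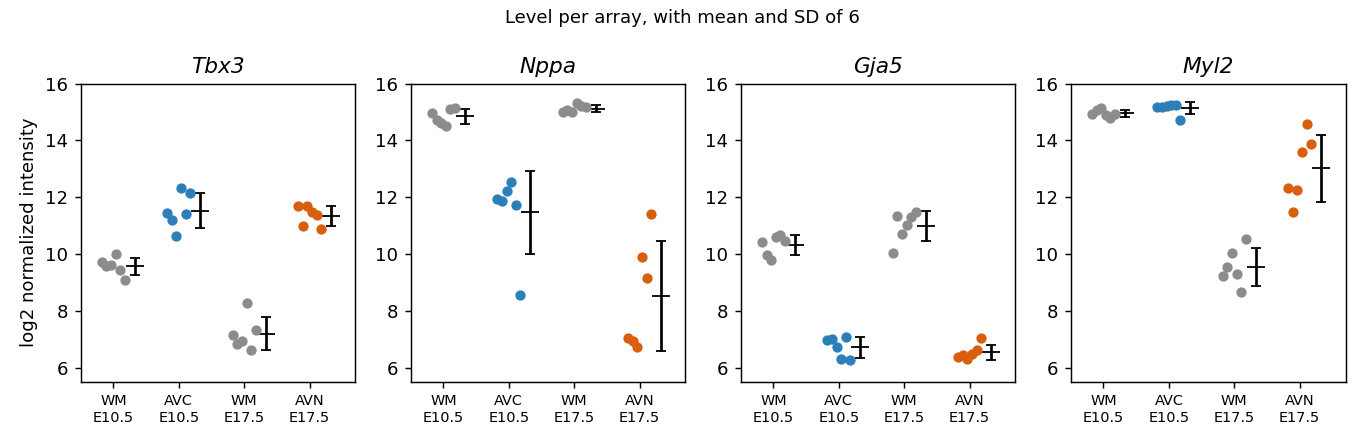
Normalized intensity (log2, vertical axis) of 4 genes on each of the 24 arrays, by group, with the mean and SD of 6 arrays in black. Tbx3 lay at 11.53 in AVC and 11.35 in AVN, Nppa and Gja5 were lower in AVC and AVN than in WM of the same stage, and Myl2 fell in WM between the stages to 9.55 while it read 13.01 in AVN.

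The E10.5 comparison asked which genes set the canal apart from chamber muscle before a node is formed. Among the largest differences upward were those of Msx1, a homeobox gene that responds to BMP signals (log2 difference 3.69 ± 0.23), the serpin gene Serpinf1 (3.62 ± 0.36), Sox9, a transcription factor of cartilage and valve mesenchyme (3.60 ± 0.41), Papss2, an enzyme that makes the sulphate donor for proteoglycans (3.39 ± 0.37), and the matrix genes Mmp2 (3.23 ± 0.44), Tgfbi (3.22 ± 0.35) and Matn4 (3.18 ± 0.49). Cyp26b1, which degrades retinoic acid, was higher by 3.16 ± 0.39. Among the largest downward, Gja5, the gene of the fast gap junction protein connexin 40, differed by -3.59 ± 0.21, the natriuretic peptide gene Nppb by -3.20 ± 0.26, the troponin gene Tnni2 by -3.19 ± 0.25, Igfbpl1 by -3.07 ± 0.22, Aldh1b1 by -2.41 ± 0.21 and the proprotein convertase gene Pcsk6 by -2.34 ± 0.21.

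Of the chamber myocardium list, 12 of 18 measured genes fell in AVC at E10.5 and none rose, with a median log2 difference of -0.84 (13 fell when adjusted over the list alone; adjusted p = 1.82e-08, and adjusted p = 0.0448 with an estimated correlation). The call with an estimated correlation was lost, at an adjusted p of 0.0514, when WM replicates 1 and 4 of E17.5 were left out. The atrial myocardium list had 5 of 12 members lower (5 over the list alone; median -0.41, adjusted p = 0.00167, and adjusted p = 0.144 with an estimated correlation), and the ventricular list 3 of 9 (4 over the list alone; median -0.57, adjusted p = 0.0142, and adjusted p = 0.264 with an estimated correlation). The ventricular call was also lost with label code 2 alone (median -0.31, adjusted p = 0.136), the code as a block (adjusted p = 0.0633) and the stricter filter (adjusted p = 0.316). Contractile genes differed less evenly. In the sarcomere list 8 of 24 fell, including Myom1 (-1.65 ± 0.29) and Myh6, the fast cardiac myosin heavy chain (-1.55 ± 0.36), while Tpm1 rose by 1.71 (8 and 1 over the list alone; median -0.68, adjusted p = 0.0115, and adjusted p = 0.606 with an estimated correlation). Tnnt2 and Myl2, which passed no test here, differed by 0.16 ± 0.21 and 0.18 ± 0.37. The SE of Myl2 takes in its wider spread at E17.5. Calcium handling genes were lower in 10 of 14 cases, among them Pln (-1.63 ± 0.30), Jph2 (-1.61 ± 0.28) and the release channel gene Ryr2 (-1.46 ± 0.30), with a list median of -0.89 (10 over the list alone; adjusted p = 4.84e-05, and adjusted p = 0.188 with an estimated correlation).

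Energy metabolism genes were lower in AVC at E10.5. Of 38 oxidative phosphorylation genes 25 fell and none rose, with Ndufa5 at -0.95 ± 0.14 (27 over the list alone; median -0.59, adjusted p = 2.16e-11, and adjusted p = 0.157 with an estimated correlation). Of 20 fatty acid oxidation genes 14 fell, among them Cpt1b, the mitochondrial importer of fatty acids, from 10.99 in WM to 9.48 in AVC (14 over the list alone; median -0.60, adjusted p = 7.1e-09, and adjusted p = 0.144 with an estimated correlation). Glycolysis genes fell in 5 of 18 cases (5 over the list alone; median -0.28, adjusted p = 0.0184, and adjusted p = 0.564 with an estimated correlation). The glycolysis call was lost with the stricter filter. Within the list of conduction and node genes, 5 of 23 rose and 4 fell (5 and 5 over the list alone), and the list as a whole did not pass its test (median -0.03, mean 0.02, adjusted p = 0.761). Tbx2, a repressor of chamber genes, rose by 1.18 ± 0.15, Msx2 by 1.39 ± 0.15, Id2 by 0.93 ± 0.19 and the T-type calcium channel gene Cacna1g by 0.87 ± 0.25. Cacna1g differed by 0.56 without AVC replicate 6, and without WM replicates 5 and 6 by 0.82, when it did not pass (adjusted p = 0.0544). Irx3 (-1.39 ± 0.21) and Vsnl1 (-1.19 ± 0.26) fell.

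The lists of BMP and TGF-beta signalling and of mesenchyme, endothelium and epicardium markers were higher in AVC at E10.5, at the preset correlation only. In the BMP and TGF-beta list 14 of 25 rose and 5 fell (the same numbers over the list alone; median 0.55, adjusted p = 0.00036, and adjusted p = 0.188 with an estimated correlation). Id1 rose by 2.05 ± 0.20 and Bmper by 1.69 ± 0.19, Bmp4 went from 10.64 in WM to 12.14 in AVC, and Bmp7 fell by 1.61. Cushion mesenchyme and fibroblast markers rose in 14 of 22 cases and fell in 1, with Twist1 at 3.05 ± 0.22 and Pdgfra at 2.62 ± 0.38 (14 and 1 over the list alone; median 1.00, adjusted p = 6.24e-08, and adjusted p = 0.163 with an estimated correlation). A further Pdgfra probe did not follow, at -0.01. Endothelium and endocardium markers rose in 17 of 20 cases, Ramp2 by 2.87 ± 0.45 and Pecam1 by 2.45 ± 0.44 (18 over the list alone; median 1.55, adjusted p = 1e-10, and adjusted p = 0.188 with an estimated correlation). Epicardium markers rose in 6 of 9 cases (8 over the list alone; median 0.74, adjusted p = 0.00067, and adjusted p = 0.278 with an estimated correlation), whereas erythroid (median -0.96, 2 higher and 1 lower of 10, adjusted p = 0.806) and leukocyte markers (median -0.33, 0 of 12 called, adjusted p = 0.281) did not pass. WM replicates 5 and 6 had the lowest means of the endothelium, mesenchyme, epicardium, erythroid and leukocyte lists in their group. Without these 2 samples, an alternative chosen after seeing the data, the list medians were 1.18 for endothelium, 0.71 for mesenchyme and 0.63 for epicardium, all still past the threshold at the preset correlation. Erythroid markers at -1.82 (adjusted p = 0.00742, and adjusted p = 0.284 with an estimated correlation) and leukocyte markers at -0.46 (adjusted p = 0.0373, and adjusted p = 0.592 with an estimated correlation) passed it too. With an estimated correlation the adjusted p of the other 3 lists was 0.19, 0.169 and 0.363. Whether a lower share of cardiomyocytes in the AVC sorts lowered the chamber, contractile, calcium and energy lists was not tested and stays open.

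In all, 3482 of 12982 genes differed between AVC and WM at E10.5 at an adjusted p under 0.05, 1656 higher and 1826 lower, and 432 and 225 of them by at least 2-fold. This balance differed with the normalization, in that 47.6% of the calls were higher here, 40.3% with 75th percentile scaling and 55.9% in the deposited values. For 1844 genes (14.2%) the values of the groups did not overlap, where chance gives 0.216%. The E10.5 descriptions carry a code of 1 or 2 whose meaning is not given. With code 1 alone 2964 genes passed, with code 2 alone 1093, and with the code as a block 4082. Without WM replicates 5 and 6, 2358 passed.

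**Figure D2:**
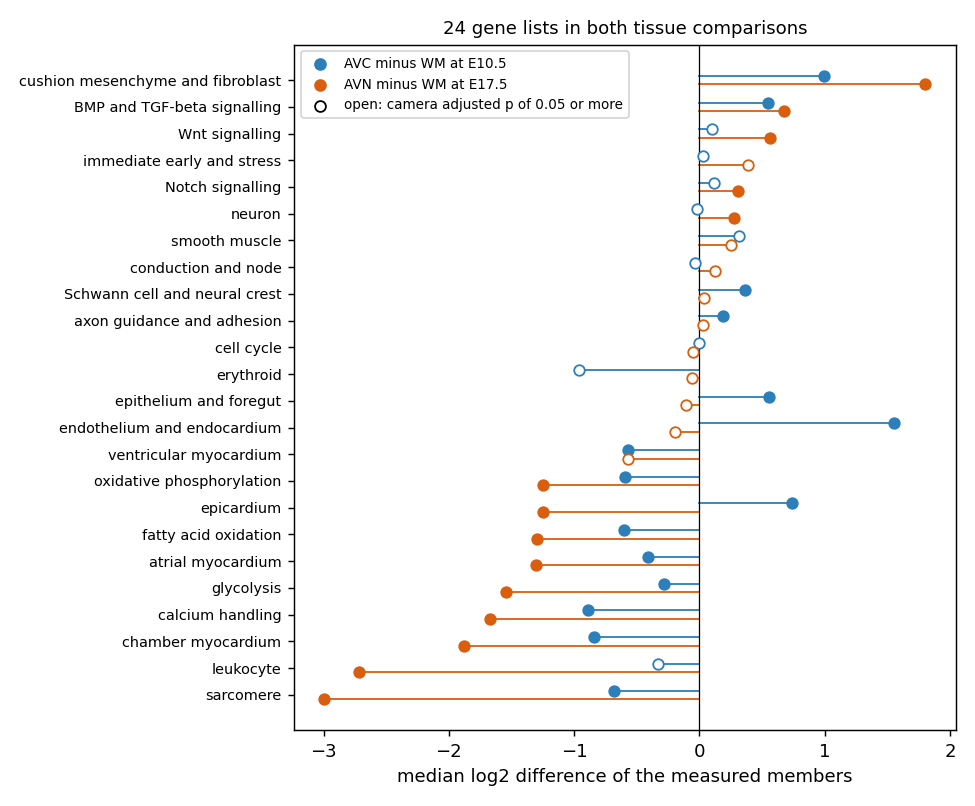
Median log2 difference (horizontal axis) of the measured members of each of the 24 gene lists, in AVC minus WM at E10.5 (blue) and AVN minus WM at E17.5 (orange). Filled points passed the set test with preset correlation at an adjusted p under 0.05. The sarcomere list lay at -0.68 and -2.99, the mesenchyme list at 1.00 and 1.80, and the endothelium list at 1.55 and -0.20.

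At E17.5 the question was which genes mark the formed node. Among the largest differences upward were Ltbp2, a latent TGF-beta binding protein (log2 difference 6.76 ± 0.30), the butyrophilin gene Btn1a1 (5.56 ± 0.23), the carbonic anhydrase gene Car3 (5.53 ± 0.23), the protease-like gene Prss35 (5.52 ± 0.34), Msx1 (5.44 ± 0.23), Rspo3, a secreted enhancer of Wnt signals (5.03 ± 0.17) and Matn4 (5.02 ± 0.49). The proteoglycan gene Prelp read 14.46 in AVN and 9.47 in WM. Among the largest downward were Nppb (-7.38 ± 0.26), Myh8, the perinatal skeletal myosin (-5.59 ± 0.44), the globin genes Hba-a1 (-5.33 ± 0.83) and Hbb-bs (-5.25 ± 0.76), the mesothelial gene Upk3b (-5.05 ± 0.57) and the atrial gene Mybphl (-4.98 ± 0.45). Several of these genes were near the floor in the dimmer group, Nppb for example above the array median on 3 of 6 AVN arrays and Car3 on 0 of 6 WM arrays, so that their differences are understated by an unknown amount.

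Contractile and calcium genes were lower in AVN than in WM at E17.5. Of 24 sarcomere genes 19 fell, including Myh6 (-4.84 ± 0.36), Myom2 (-4.65 ± 0.41) and the myosin-binding protein gene Mybpc3 (-4.00 ± 0.40), and 2 rose (19 and 2 over the list alone; median -2.99, adjusted p = 1.28e-08, and adjusted p = 0.229 with an estimated correlation). Those 2 were Tpm1 (1.68 ± 0.37) and Myl2, the ventricular regulatory light chain, at 3.47 ± 0.37. The difference of Myl2 was larger in replicates 4 to 6 alone than in replicates 1 to 3 alone. Tnnt2 fell less, at -0.80 ± 0.21. The list median was -3.48 for replicates 1 to 3 alone and -2.24 for replicates 4 to 6 alone. Calcium handling genes fell in 10 of 14 cases, including Hrc (-4.04 ± 0.35) and Casq2 (-3.51 ± 0.35), and Ryr2 read 8.84 in AVN and 12.54 in WM (11 over the list alone; median -1.67, adjusted p = 9.31e-07, and adjusted p = 0.144 with an estimated correlation). Chamber myocardium genes fell in 12 of 18 cases and rose in 2, with Gja5 at -4.44 ± 0.21 and the creatine kinase gene Ckm at -4.71 ± 0.39 (12 and 2 over the list alone; median -1.88, adjusted p = 1.15e-06, and adjusted p = 0.0592 with an estimated correlation). Atrial genes fell in 10 of 12 cases, with the atrial light chain Myl7 at 11.27 in AVN and 14.77 in WM (10 over the list alone; median -1.31, adjusted p = 1.15e-06, and adjusted p = 0.0448 with an estimated correlation). This last call was lost as well without WM replicates 1 and 4 of E17.5 (adjusted p = 0.0514) or WM replicates 5 and 6 of E10.5 (adjusted p = 0.0576). The ventricular list had 2 higher and 3 lower of 9 members and did not pass (median -0.57, adjusted p = 0.333).

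Energy metabolism was lower across its lists in AVN. Oxidative phosphorylation genes fell in 33 of 38 cases, with Cox8b at -3.77 ± 0.34 (33 over the list alone; median -1.25, adjusted p = 2.35e-17, and adjusted p = 0.12 with an estimated correlation). Fatty acid oxidation genes fell in 18 of 20, with Cpt1b at -3.38 ± 0.23 (19 over the list alone; median -1.30, adjusted p = 1.13e-10, and adjusted p = 0.107 with an estimated correlation). Glycolysis genes fell in 16 of 18, with Pgam2 at -3.46 ± 0.35 and Ldhb at -2.55 ± 0.17 (16 over the list alone; median -1.54, adjusted p = 1.13e-10, and adjusted p = 0.157 with an estimated correlation). Within the conduction and node list 7 members rose and 7 fell of 23 (9 and 7 over the list alone). It did not pass, with a median of 0.12, a mean of -0.16 and an adjusted p of 0.891. Cacna1g rose by 3.24 ± 0.25, Id2 by 1.32 ± 0.19, Tbx2 by 1.06 ± 0.15 and Msx2 by 0.65 ± 0.15. Popdc2, a cyclic AMP-binding membrane protein, fell by 3.49, as did Kcnj5, a channel subunit of the acetylcholine-activated potassium current (-2.45 ± 0.23), Irx3 (-1.52 ± 0.21) and Vsnl1, from 9.78 in WM to 7.29 in AVN. Probes for the pacemaker channel gene Hcn4 and for Bmp2 did not pass the brightness filter and were not tested.

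Signalling lists were higher in AVN. BMP and TGF-beta genes rose in 17 of 25 cases and fell in 2, Bmper by 4.71 ± 0.19 and Bmp4 by 2.42 ± 0.24, while Bmp7 fell by 3.44 (17 and 2 over the list alone; median 0.67, adjusted p = 1.5e-05, and adjusted p = 0.149 with an estimated correlation). Wnt genes rose in 12 of 22, including Wnt9b at 2.61 ± 0.15 and the target gene Axin2 at 2.04 ± 0.16 (12 over the list alone; median 0.56, adjusted p = 0.000561, and adjusted p = 0.144 with an estimated correlation). Notch genes rose in 10 of 18 and fell in 1, led by Heyl at 2.70 ± 0.16 (10 and 1 over the list alone; median 0.31, adjusted p = 0.0213, and adjusted p = 0.188 with an estimated correlation). Notch1 rose by 1.16 ± 0.39, but without WM replicate 5 it differed by 0.91 and its adjusted p was 0.0538. The call of the Notch list was lost with replicates 1 to 3 alone.

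Markers of other cell types moved apart at E17.5. Cushion mesenchyme and fibroblast genes were higher in AVN in 17 of 22 cases and lower in none, with Has2, the hyaluronan synthase of the cushions, at 3.99 ± 0.21, Sox9 at 3.34 ± 0.41, Lum at 3.24 ± 0.26 and Twist1 at 3.09 ± 0.22 (17 over the list alone; median 1.80, adjusted p = 3.02e-08, and adjusted p = 0.157 with an estimated correlation). Leukocyte markers were lower in AVN in 12 of 12 cases, Laptm5 by -4.70 ± 0.62 and the complement gene C1qb by -3.85 ± 0.32 (12 over the list alone; median -2.72, adjusted p = 3.76e-08, and adjusted p = 0.188 with an estimated correlation). Epicardium markers were lower in 6 of 9 cases and higher in 1, with the mesothelial gene Msln at -4.29 ± 0.32 (7 and 1 over the list alone; median -1.25, adjusted p = 0.012, and adjusted p = 0.407 with an estimated correlation). Endothelium markers did not move as a list, with 7 higher and 4 lower of 20 (7 and 5 over the list alone; median -0.20, mean 0.10, adjusted p = 0.737), since Cldn5 rose by 2.56 ± 0.31 and Emcn fell by 1.77. Erythroid markers had 1 higher and 3 lower of 10 (median -0.06, adjusted p = 0.376). With the stricter filter the calls of the leukocyte and epicardium lists were lost. WM replicates 1 and 4 had the highest means of the leukocyte, epicardium, endothelium and erythroid lists in their group. Without these 2 samples, chosen after seeing the data, the leukocyte median was -2.28 (adjusted p = 7.95e-08, and adjusted p = 0.15 with an estimated correlation) and the epicardium median -0.81, which no longer passed (adjusted p = 0.0582).

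**Figure D3:**
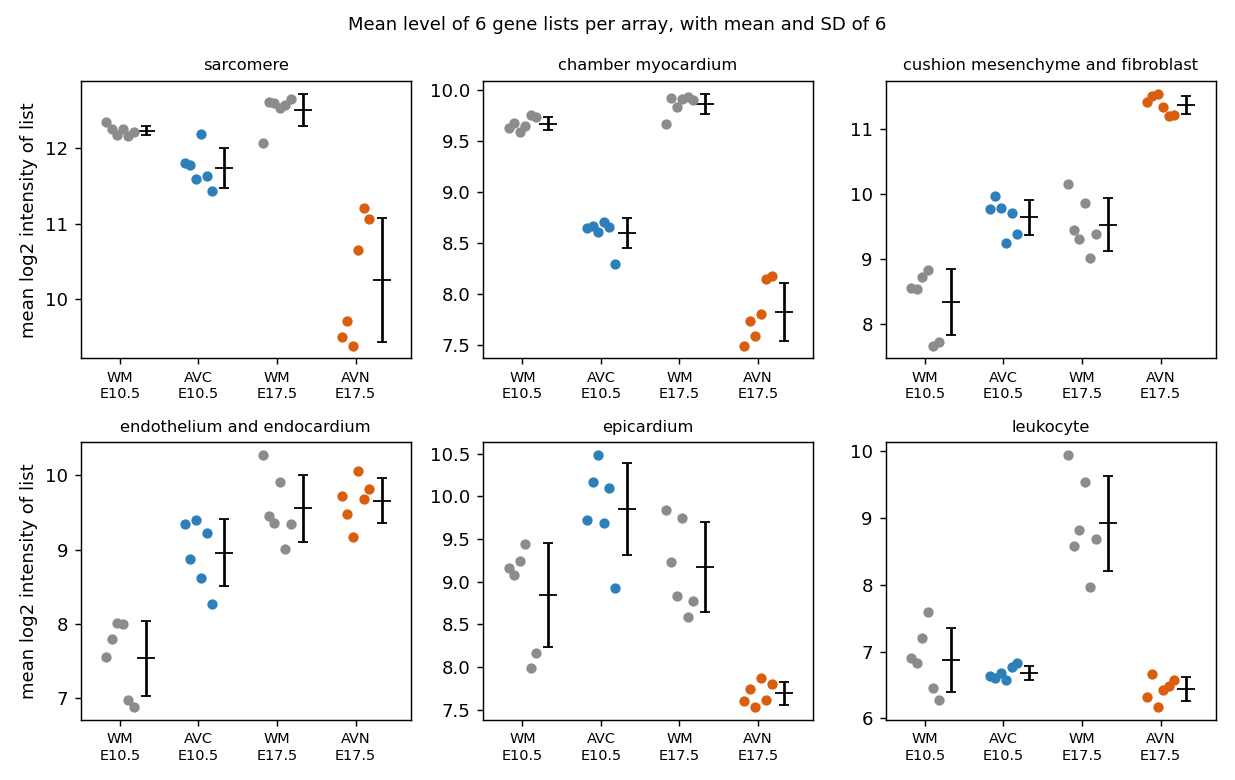
Mean normalized intensity (log2, vertical axis) over the measured members of 6 gene lists on each array, by group, with the mean and SD of 6 arrays in black. AVN arrays fell into replicates 1 to 3 and 4 to 6 for the sarcomere list, WM at E17.5 spanned 7.96 to 9.94 for the leukocyte list, and WM replicates 5 and 6 at E10.5 lay lowest for the endothelium and mesenchyme lists.

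Altogether 5852 of 12982 genes differed between AVN and WM at E17.5, 2942 higher and 2910 lower, and 813 and 936 by at least 2-fold. The groups did not overlap for 3234 genes (24.9%, against 0.216% by chance). Arrays of replicates 1 to 3 were brighter at E17.5 than those of replicates 4 to 6 in both tissues, with array means of 370.3 to 432.5 against 264.9 to 363.0 units. Replicates 1 to 3 alone gave 4367 genes and replicates 4 to 6 alone 3507, and 5999 passed with these subsets as a block. Without WM replicates 1 and 4, 5990 passed.

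Many of the genes that set AVC apart also set AVN apart. Of the 2487 genes called at both stages, 2288 differed in the same direction. 1047 were higher in both, where independent lists would share 375.3 (odds ratio 8.55), and 1241 were lower in both, against 409.3 (odds ratio 12.05). No arrays are shared between the comparisons, but the calls are not independent. Both comparisons used the same variance per gene, estimated over all groups, so a gene with a small variance passes more easily in both. The split by reporter line was also the same at both stages. The expected numbers and odds ratios take neither into account, so they do not measure how much tissue difference is shared. Across genes the log2 differences of the stages correlated with Pearson's r = 0.57 and Spearman's rho = 0.55, and genes are not independent replicates. Id1 (2.05 and 2.09), Twist1 (3.05 and 3.09), Sox9 (3.60 and 3.34), Tbx2 and Igfbpl1 (-3.07 and -3.16) had like sizes at both stages, and for none of them did the difference between stages pass its test.

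The difference itself passed the test for 3030 genes, 1450 with a more positive and 1580 with a more negative value at E17.5. In the deposited values 2474 genes passed, 37.2% of them with a more positive value. Among those shifted upward were Ltbp2 (5.13 ± 0.43), Btn1a1 (4.50 ± 0.32), the cartilage collagen gene Col2a1 (4.44 ± 0.23), Pcsk6 (4.23 ± 0.30) and Cacna1g (2.37 ± 0.35). Pcsk6 went from -2.34 at E10.5 to 1.89 at E17.5, and Col2a1 from -0.80 to 3.64. Among those shifted downward were Upk3b (-6.94 ± 0.80), the keratin gene Krt7, at 1.68 and then -4.32, Laptm5 (-5.89 ± 0.88) and Myh8 (-5.57 ± 0.62). Upk3b had been higher in AVC by 1.89 and Krt7 by 1.68, calls that were lost without WM replicates 5 and 6 of E10.5, at 0.79 (adjusted p = 0.173) and 0.73 (adjusted p = 0.322). Leaving out any of AVC replicates 2, 3 and 5 or WM replicates 5 and 6 singly also ended the E10.5 call of Krt7, at 1.25 to 1.62. By list, the sarcomere difference grew by -2.07 at the median (19 of 24 members shifted downward and 1 upward, 19 and 1 over the list alone; adjusted p = 4.45e-09, and adjusted p = 0.22 with an estimated correlation). The glycolysis list shifted by -1.07 (13 of 18 members, 15 over the list alone; adjusted p = 6.3e-11, and adjusted p = 0.154 with an estimated correlation). The endothelium list shifted by -1.62 (11 of 20 members, 12 over the list alone; adjusted p = 5.4e-05, and adjusted p = 0.347 with an estimated correlation).

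Between the stages, AVN exceeded AVC most in genes such as Prelp (7.34 ± 0.28), the calcification inhibitor gene Mgp (7.14 ± 0.20), the dermatopontin gene Dpt (6.24 ± 0.24) and Ltbp2 (6.03 ± 0.30), and lay below it in Upk3b (-5.88 ± 0.57), the keratin genes Krt8 (-5.12 ± 0.33) and Krt7 (-4.28 ± 0.56) and the embryonic globin gene Hbb-bh1 (-4.48 ± 0.76). In WM, Myom2 (7.29 ± 0.41), Myh8 (7.08 ± 0.44), Ckm (6.52 ± 0.39), the tenascin gene Tnxb (5.14 ± 0.32) and Mgp (4.74 ± 0.20) were higher at E17.5. Col2a1 (-5.79 ± 0.16), Myl2 (-5.41 ± 0.37), Hbb-bh1 (-5.30 ± 0.76) and the stem cell gene Trim71 (-3.69 ± 0.26) were lower. Cell cycle genes fell with stage in 25 of 28 cases in the Tbx3-sorted groups and in 24 of 28 in WM (25 and 25 over the list alone). Their medians were -0.99 (adjusted p = 4.34e-08, and adjusted p = 0.188 with an estimated correlation) and -0.76 (adjusted p = 8.34e-08, and adjusted p = 0.188 with an estimated correlation). In total 7113 genes differed between AVN and AVC, 3393 higher and 3720 lower, and 6439 between the WM groups, 3088 higher and 3351 lower. This balance turned with 75th percentile scaling, where 57.8% and 54.1% of the calls were higher, against 47.7% and 48.0% here. All samples of a stage shared 1 range of array brightness, so stage and array brightness cannot be told apart in these 2 comparisons.

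Genes that neighbour Nppa differed with it. In the gene order of the reference assembly GRCm38.p6 on chromosome 4, the 10 tested genes nearest to Nppa, 5 on each side, had a median log2 difference of -0.65 at E10.5 and -0.71 at E17.5. These medians lay at the 0.03 and 0.05 percentile of 10000 random windows of neighbouring genes. 6 of the 10 were called lower in AVC and 9 in AVN, and none higher. Mfn2, a mitochondrial fusion gene, was lower by -1.79 ± 0.12 in AVC and -2.37 ± 0.12 in AVN, Plod1, a collagen-modifying enzyme, by -1.30 ± 0.10 and -0.74 ± 0.10, and 2510039O18Rik by -1.83 ± 0.07 and -1.55 ± 0.07. Clcn6 (-0.39 ± 0.08 and -0.53 ± 0.08) and Agtrap (-0.90 ± 0.14 and -0.38 ± 0.14) were also lower at both stages, although the E17.5 value of Agtrap lost its call when any of 6 single samples was left out. At E10.5 Mad2l2, Fbxo6 and Fbxo44 differed by -0.11 ± 0.12, 0.22 ± 0.10 and -0.32 ± 0.22, none past the threshold, and at E17.5 by -0.68 ± 0.12, -0.60 ± 0.10 and -1.89 ± 0.22, all called lower. The 10 tested genes nearest to Tbx3 on chromosome 5 had medians of 0.01 and -0.01, at the 67.2 and 42.8 percentile. The neighbours of Nppa were chosen after the values of Nppb, Mfn2 and 2510039O18Rik had been seen. The other 7 alone lay at the 1.36 and 1.24 percentile of the same positions in random windows. Tbx5 had been seen among the neighbours of Tbx3 (0.16 ± 0.18 and -1.01 ± 0.18).

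**Figure D4:**
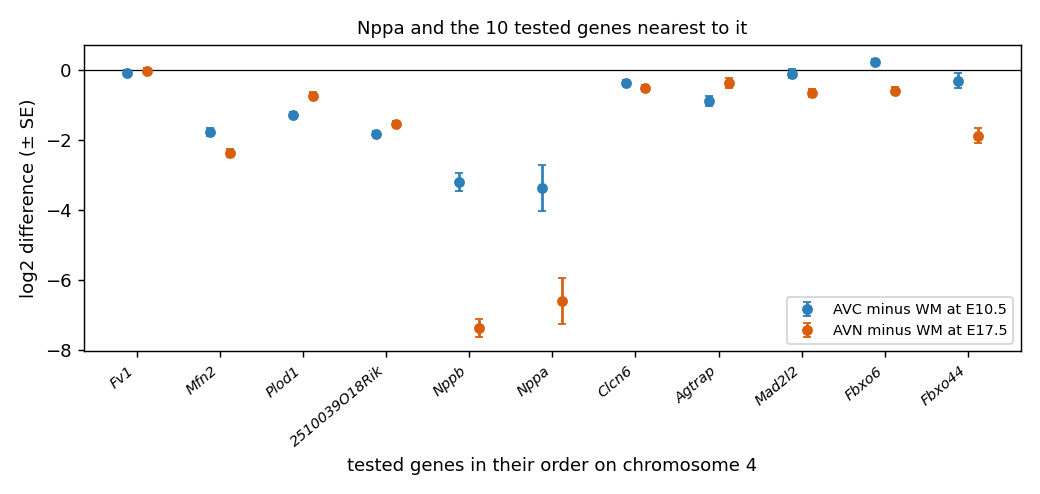
Log2 difference (vertical axis, ± SE, 6 arrays per group) of Nppa and the 5 tested genes on each side of it, in their order on chromosome 4, for AVC minus WM at E10.5 (blue) and AVN minus WM at E17.5 (orange). Mfn2, Plod1, 2510039O18Rik, Nppb, Clcn6 and Agtrap were below 0 at both stages.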

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

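All tests of explanations in this part were chosen after the results were seen, except the splits of the samples, which were planned. In 468 series of 6 values, for named genes and list means, 36 had a value far from the other 5, where chance flags about 1 in 20. The named genes were picked from those the naming rule gives after a first count of such values had been seen, so these numbers hold for the genes named and are no rate over all genes. 9 of the 36 were WM replicate 1 of E17.5, 8 AVC replicate 6 and 7 AVC replicate 4. In AVC replicate 6, Nppa (8.54), Nppb (8.90), Car3 (8.58), Myl2 (14.73) and the means of the chamber (8.30) and immediate early lists (8.66) were low, and Cyp26b1 (13.87) and Cacna1g (9.14) high. In AVC replicate 4, Serpinf1 (11.86) and Ccnd1 (12.07) were low, and Popdc2 (12.04), Bmp7 (10.51), Hbb-bh1 (11.88), Agtrap (10.62) and the glycolysis mean (12.45) high. In WM replicate 1 of E17.5, Myh6 (10.84), Cpt1b (10.60), Hrc (12.01), the chamber (9.67), sarcomere (12.08) and atrial means (10.51) and Fbxo44 (7.81) were low, and Mgp (11.99) and the Schwann cell mean (8.03) high. The remaining values were Matn4 at 13.70 and Tnni2 at 8.29 in AVN replicate 6, Dpt at 12.50 in AVN replicate 1, the axon guidance mean at 8.98 in AVN replicate 4, Myl7 at 14.47 in WM replicate 5 of E17.5 and Hbb-bs at 7.54 in AVC replicate 3. In WM of E10.5 they were Msx2 at 7.12 and Myom2 at 6.85 in replicate 1, Mybphl at 12.23 and Fbxo44 at 7.68 in replicate 4, Ccnd1 at 11.08 in replicate 5 and Agtrap at 11.28 in replicate 6.

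The tissue difference at E17.5 minus that at E10.5 passed the test for 66 of 93 genes named in the text. It was positive, as a log2 difference, for Ltbp2 (5.13), Btn1a1 (4.50), Col2a1 (4.44), Pcsk6 (4.23), Prss35 (4.0), Prelp (3.94), Car3 (3.49), Myl2 (3.29), Bmper (3.03), Heyl (2.54), Dpt (2.49), Rspo3 (2.45), Mgp (2.40), Cacna1g (2.37), Lum (2.35), Wnt9b (2.29), Syt1 (2.25), Tbx3 (2.21), Msx1 (1.75), Has2 (1.44), Unc5c (1.35), Hey2 (1.24), Axin2 (1.05) and Plod1 (0.55). It was negative for the chamber, contractile and metabolic genes Nppa (-3.22), Nppb (-4.18), Gja5 (-0.85), Mybphl (-3.27), Ckm (-3.92), Myh6 (-3.29), Myh8 (-5.57), Myl7 (-2.97), Myom1 (-1.75), Myom2 (-4.60), Mybpc3 (-2.83), Tnnt2 (-0.96), Pln (-1.54), Ryr2 (-2.24), Hrc (-2.75), Casq2 (-2.39), Popdc2 (-2.75), Kcnj5 (-1.87), Vsnl1 (-1.30), Cpt1b (-1.88), Ndufa5 (-0.81), Cox8b (-3.13), Pgam2 (-2.92) and Ldhb (-2.25). It was also negative for Upk3b (-6.94), Krt7 (-6.0), Krt8 (-3.42), Msln (-4.85), Laptm5 (-5.89), C1qb (-3.19), Hba-a1 (-3.68), Hbb-bs (-3.38), Pecam1 (-2.77), Emcn (-3.55), Tgfbi (-1.94), Bmp7 (-1.83), Aldh1b1 (-2.05), Msx2 (-0.74), Mfn2 (-0.58), Mad2l2 (-0.56), Fbxo6 (-0.82) and Fbxo44 (-1.57). 15 lists shifted, by medians of -1.04 for chamber, -1.11 for atrial myocardium, -2.07 for sarcomere, -1.12 for calcium handling, -0.66 for oxidative phosphorylation, -0.64 for fatty acid oxidation, -1.07 for glycolysis, -1.62 for endothelium, -2.37 for epicardium, -2.35 for leukocytes, -0.52 for epithelium, 0.46 for BMP and TGF-beta, 0.38 for Wnt, 0.26 for neurons and 0.48 for mesenchyme. With an estimated correlation 0 of these passed, the lowest being the atrial list (adjusted p = 0.0891 with an estimated correlation).

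For the lower sarcomere genes of AVN at E17.5, a lower share of cardiomyocytes made up by all other cell types alike would raise the markers of each, but the lowest of 4 such list medians, that of leukocytes, was -2.717 while mesenchyme stood at 1.80. Dilution of a single kind of cardiomyocyte as the whole cause would lower genes that only it expresses by one amount. Myl2 rose by 3.47 ± 0.37, which dilution alone would not give for this gene. It rose by more in replicates 4 to 6 alone than in 1 to 3 alone. The sarcomere list median was also less low there, at -2.242 against -3.481. Less dilution in replicates 4 to 6 could give both, so this pattern does not speak against dilution as part of the cause. The 21 sarcomere genes above the array median on all arrays had an SD of 5.593 times their median standard error (4.27 without Myl2). This spread takes in Tpm1, which rose too, and bright genes whose differences can be understated. For the 19 that differed downward the ratio was 3.24, and for 9 of middle brightness 3.53, or 2.41 without Myl3. The ratios therefore do not decide on dilution for the list as a whole. Array brightness does not account for the lower sarcomere genes, since the list median was -2.242 in the subset of replicates where it was weakest. Dilution as part of the cause, a larger share of mesenchymal cells in some AVN sorts, more than one kind of cardiomyocyte, and a true difference of nodal cells stay open.

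In WM at E17.5, the leukocyte, epicardium, endothelium and erythroid lists differed between replicates. All 4 lists had the same pair of highest arrays, replicates 1 and 4 (value 4). This restates what was seen and adds no support to different shares of other cell types in the sorts, which stay open. None of these lists shares a measured gene with another list. Array brightness at E17.5 separated replicates 1 to 3 from 4 to 6 in 0 of the 4 lists. This follows from replicates 1 and 4, which lie in different brightness subsets, being the highest, so it is no separate test. A difference in the dissected tissue stays open too and was not tested.

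Chance was examined with 100 splits per comparison, the real one included. For 4 comparisons only 1 of 100 splits, the real one, gave as many genes. This is the lowest share that 100 splits can give, and it makes chance unlikely. The numbers were 3482 against at most 1889 in another split at E10.5, 5852 against 3924 at E17.5, 7113 against 4234 for AVN minus AVC, and 6439 against 3651 for WM. For the difference between stages 2 of 100 splits gave as many as the real 3030, the other one 3935. These splits exchange the tissue labels within both stages and so remove the tissue difference itself as well. They cannot tell whether the difference between stages exceeds chance. Splits into replicates 1 to 3 and 4 to 6 gave 0 genes at E10.5 and 25 at E17.5. In these splits each subset held both tissues, so the tissue difference widened the spread and few genes could pass. The 2 counts therefore do not show that the subsets were alike. Within AVN alone, 101 genes differed between these subsets, and 0 within each of the other 3 groups.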

How the results depend on the processing

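The alternatives that leave out WM replicates 1 and 4 at E17.5 or 5 and 6 at E10.5, or use replicates 1 to 3 and 4 to 6 of E17.5 as a block or alone, were chosen after seeing the data; the others were planned. No count of changed genes, shared calls or lists moved by more than 1.5 times under no background correction, 75th percentile scaling, quantile normalization within stage, the deposited values, either filter, the mean of a gene's probes, fits on 12 samples, eBayes with trend and robust, or array weights. Leaving out each sample in turn gave 2985 to 3657 genes at E10.5, 5513 to 5934 at E17.5, 2787 to 3239 for the difference between stages, 6812 to 7252 for AVN minus AVC, 6121 to 6527 for WM, 2013 to 2454 shared calls and 59 to 62 lists. A 2-fold minimum left, in that order, 657, 1749, 1186, 2085, 1615 and 386, and an adjusted p under 0.01 left 2284 at E10.5, 1984 for the difference and 1508 shared, since both thresholds are stricter by construction. Code 2 alone gave 1093 genes at E10.5, where code 1 alone, with as many samples, gave 2964, and 55 gene values lost their call with code 2 against 6 with code 1. Replicates 4 to 6 alone gave 3507 genes at E17.5 and 1 to 3 alone 4367. The causes were not tested. An estimated correlation left 2 of 60 list calls, 0 without WM replicates 1 and 4 of E17.5 (chamber list at E10.5 and atrial list at E17.5, each adjusted p = 0.0514) and 1 without WM replicates 5 and 6 of E10.5 (chamber list at E10.5, adjusted p = 0.0376). Over all samples the estimates ran from 0.005 for the Schwann cell list to 0.708 for the leukocyte list, against the preset of 0.01. The sarcomere list had 0.532 and the oxidative phosphorylation list 0.308. For such lists the calls at the preset rest on a lower correlation than the samples gave. At E10.5 the share of higher calls was 47.6% in the values reported, 40.3% with 75th percentile scaling and 55.9% in the deposited values, and for WM between the stages 48.0%, 54.1% and 51.8%. In AVN minus AVC, 75th percentile scaling put the median of all genes at 0.139, against 0.005 in the values reported, and moved the share of higher calls from 47.7% to 57.8%, and the deposited values gave 37.2% higher calls for the difference between stages where 47.9% were higher in the values reported; the causes were not tested. By list, code 2 alone ended the calls of the ventricular and axon guidance lists at E10.5, the code as a block that of the ventricular list, replicates 1 to 3 alone those of Notch (adjusted p = 0.0757) and neurons (adjusted p = 0.0515) at E17.5, and fits on 12 samples that of neurons (adjusted p = 0.0588). The stricter filter ended those of glycolysis (adjusted p = 0.0779), epithelium (adjusted p = 0.165) and ventricular genes at E10.5 and of neurons (adjusted p = 0.408), epicardium (adjusted p = 0.105) and leukocytes (adjusted p = 0.0808) at E17.5. No gene or list value changed from called in one direction to called in the other.

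Of 317 gene values in the contrasts, 11 lost their call when some single sample was left out, Popdc2, Mybpc3 and Trim71 at E10.5 and Ramp2 at E17.5 among them, and 1 of 48 list values gained one. Same-numbered samples did not deviate together at E10.5 (correlations -0.134 to 0.194, with 0 of 6 correlating best with their own number). At E17.5 the correlations were 0 to 0.212, with 2 of 6 best with their own number, which leaves a weak pairing possible. The numbers were taken to name samples only. With the replicate block 3506 genes passed at E10.5, 5881 at E17.5, 3063 for the difference and 2335 were shared; stage contrasts cannot be estimated with it. The files used here name no chip, so no block was set up by chip. The E10.5 label code was run as a block, and the sources used here do not say whether it stands for chips. Without detection p-values, the signal over background of a dim probe is not known here.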

Other observations

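The test of the genes next to Nppa and the values without single pairs of samples were chosen after the results were seen, and that of the genes next to Tbx3 before, although the value of Tbx5, 1 of its 10 neighbours, had been seen. All 9 measured members of the ventricular list differed downward from AVC to AVN (9 over the list alone; median -2.12, adjusted p = 0.000113, and adjusted p = 0.149 with an estimated correlation), and 8 of 9 from WM at E10.5 to WM at E17.5 (8 over the list alone; median -1.61, adjusted p = 6.22e-05, and adjusted p = 0.144 with an estimated correlation). Myl2 read 14.96 ± 0.13 (SD, n = 6) in WM and 15.13 ± 0.20 in AVC at E10.5, then 9.55 ± 0.66 in WM and 13.01 ± 1.17 in AVN at E17.5. Myl2 differed between AVN and WM by 2.42 in replicates 1 to 3 alone and by 4.52 in 4 to 6 alone. The atrial list had 7 members higher and 2 lower of 12 between the WM stages and did not pass (median 0.55, adjusted p = 0.146). From AVC to AVN it had 1 higher and 6 lower and did not pass (median -0.46, adjusted p = 0.0527). The share of atrial and ventricular cells in the sorts was not tested. The stage differences of Myl2 and the ventricular list need not be changes within 1 kind of muscle. Endothelium markers rose from WM at E10.5 to WM at E17.5 in 18 of 20 cases (18 over the list alone, median 1.94, adjusted p = 7.26e-08, and adjusted p = 0.229 with an estimated correlation). Leukocyte markers rose in 11 of 12 (11 over the list alone, median 2.17, adjusted p = 1.15e-06, and adjusted p = 0.229 with an estimated correlation). Both lists were lowest in WM replicates 5 and 6 of E10.5 and highest in WM replicates 1 and 4 of E17.5, so these sizes rest partly on those samples.

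The other lists passed their tissue test at 1 stage at most. Axon guidance genes were higher in AVC in 13 of 31 cases and lower in 5 (15 and 5 over the list alone; median 0.19, adjusted p = 0.0097, and adjusted p = 0.229 with an estimated correlation), a call lost with label code 2 alone (adjusted p = 0.0641), and at E17.5 the list did not pass (median 0.03, adjusted p = 0.174), although Unc5c, a netrin receptor, rose by 2.48 ± 0.23 and 3.83 ± 0.23. Schwann cell and neural crest genes were higher in AVC in 3 of 8 cases (3 over the list alone; median 0.36, adjusted p = 0.00499, and adjusted p = 0.107 with an estimated correlation) and did not pass at E17.5 (median 0.04, with a mean just below 0, adjusted p = 0.792). Neuron genes did not pass at E10.5 (median -0.02, mean 0.14, adjusted p = 0.634) and were higher in AVN in 8 of 17 cases and lower in 1 (8 and 1 over the list alone; median 0.28, adjusted p = 0.0321, and adjusted p = 0.293 with an estimated correlation). Without WM replicates 1 and 4 of E17.5, chosen after seeing the data, the neuron list no longer passed (median 0.33, adjusted p = 0.055). Syt1 rose by 1.88 ± 0.23 on its brighter probe and read -0.29 on the other. Epithelium genes were higher in AVC in 3 of 9 cases (6 over the list alone; median 0.56, adjusted p = 0.00641, and adjusted p = 0.246 with an estimated correlation) and did not pass at E17.5 (median -0.11, adjusted p = 0.313). Notch and Wnt genes at E10.5 did not pass (medians 0.12 and 0.10, adjusted p = 0.0925 and 0.225), nor did smooth muscle (0.32 and 0.25, adjusted p = 0.0655 and 0.198), immediate early (0.03 and 0.39, adjusted p = 0.403 and 0.0856) or cell cycle genes (0.00 and -0.05, adjusted p = 0.466 and 0.481) at either stage. Ccnd1, a cyclin gene of the last list, was nevertheless higher in AVC by 1.17 ± 0.18 and in AVN by 1.69 ± 0.18, and Hey2, a Notch target of ventricular muscle, lower in AVC by -0.96 ± 0.09.

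If the lower level of genes next to Nppa in the Tbx3-sorted groups came from extra copies of them on the Nppa reporter BAC, whose insert is not given in the sources used here, the 7 neighbours not seen when the pattern was noticed would also stand below random windows at both stages. The higher of their 2 percentiles was 1.36, so extra copies in the WM samples may account for part of the differences of the genes lower at both stages. The E17.5 percentile rests partly on Mad2l2, Fbxo6 and Fbxo44, lower at E17.5 only, with shifts between stages (-0.56, -0.82 and -1.57) that a fixed number of copies would not give by itself. Among the genes lower at both stages, Nppb (-4.18) and Mfn2 (-0.58) also shifted downward, and Plod1 (0.55) upward. A fixed number of copies would not give these shifts by itself either. The neighbours of Tbx3 were not higher in the Tbx3 reporter groups, with a lower percentile of 42.75. The insert of the Tbx3 BAC is not given either, so it is not known which of these neighbours it could carry. This value therefore does not decide on extra copies there. A chamber expression of the Nppa neighbours themselves stays open, because reporter line and tissue were the same split in every sample, and it was not tested.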
